A study of Drosophila melanogaster with 2 samples.

How the data were processed

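ChIP-seq was performed on whole Drosophila melanogaster embryos of 0 to 24 h from a line that expresses a peb-eGFP fusion protein, with an antibody against GFP and chromatin sheared by sonication to 200 to 800 bp, per the labels. There were 2 biological replicates in 1 group. The label that names the antibody target gives peb, and the description states that the precipitation used anti-GFP.

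Each replicate had a ranked and a thresholded peak list, and the whole experiment had a pair of thresholded lists with a ranked list behind each, 8 lists in all. The authors named the smaller of the pair conservative, and the larger is called optimal here. Each list of the pair was tied to the ranked list that holds all its peaks with the same coordinates and score. Coordinates are on dm6, per the labels. Peaks were called on each replicate's alignments for the replicate lists and on those of both replicates for the lists of the experiment, with a further file that also stands behind the fold-over-control tracks and was taken here as the control, per the file headers. The authors thresholded them by the irreproducible discovery rate (IDR). The thresholded lists were made with a further input whose kind is not given in the sources used here, and neither is the aligner or the peak caller. The signal value of each peak was deposited by the authors' pipeline and is the peak's own value; it was used to describe and rank peaks within a list, and values of different lists are not on a common scale. The deposited score is the scaled IDR, capped at 1000, and in the ranked lists it follows the deposited −log10 of the global IDR. Every thresholded peak had a score of 830 or more, a global IDR of 0.01. The 8 last columns of each ranked list hold values of the inputs that could not be mapped to a sample and were not used. Alignments and coverage tracks were not analysed here. The lists give no read numbers, so intervals given with shares cover the counting of peaks or genes only.

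Summits were placed on the genome sequence of the same assembly and on Ensembl release 115 (BDGP6.54). All peak ends lay within the chromosome lengths. Tests used the 7 main chromosomes. Analyses were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Overlap of lists required 1 bp or more. Shares near TSSs (1000 bp either side, all transcripts of protein-coding genes), shares per annotation class and overlaps were compared with 1000 random placements of the same peaks on the same chromosome, with two-sided permutation p values. Classes were assigned in the order promoter, 5′ UTR, coding exon, 3′ UTR, intron, other exon, intergenic. Introns were the bases of a gene outside every exon, so intron and other exon cannot overlap and their order has no effect. Signal values of matched peaks were compared by Spearman correlation with 100000 resamples. Chromosomes were compared with their lengths by a chi-square test and, for X against the autosomal arms, an exact binomial test.

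A gene was called bound when a summit lay within 1000 bp of one of its TSSs. The 27 gene lists were compared with all other protein-coding genes by Fisher's exact test (two-sided), adjusted over the list alone, that is over the 27 lists, by Benjamini-Hochberg. There were 8 older gene symbols, matched through the synonyms of the reference annotation, after which all members were found. For sequence, each summit with 100 bp either side was searched for 15 patterns and for all 6-mers on both strands, against windows centred 1000 bp either side that overlap no peak, with Fisher's exact test and Benjamini-Hochberg adjustment. The threshold was an adjusted p of 0.05 throughout. Intervals of shares are exact (Clopper-Pearson) at 95%.

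Gene lists, patterns, tests, the rule for named genes and most alternatives were fixed before the data were examined. The rule named the 15 strongest peaks of the optimal list at promoters that overlapped a peak of both replicates, the 5 strongest peaks anywhere, up to 4 bound members per gene list with the strongest peaks, every gene of the hindsight list, and the 3 strongest peaks of each replicate that overlapped none of the other. Bound members beyond 4 in the Notch and JNK lists were named after their values were seen. The alternatives were a stricter score, other definitions of overlap, promoter and gene, matched random gene lists (10000 draws by gene length and number of TSSs), windows of 50 and 200 bp either side, controls matched on GC content in steps of 5% and on TSS distance (2 per summit), the conservative list, and each replicate's own list in place of the joint one. No paired analysis applies, since there is 1 group.

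The tests were checked on simulated data with known answers on the same genome. With 2800 simulated peaks, a planted excess of 31.8 percentage points at TSSs was recovered as 31.5, and a planted overlap of 70% as 70.4%. A planted 6-mer came out as rank 1 of 2080, and none was called among unaltered random sites. Both checks used flanks of randomly placed sites, whereas real summits had 36.4% GC against 42.6% in flanks. They do not cover such a difference in composition. Matched controls were checked for their mean GC content alone. For gene lists, a share of 40% planted in the ribosomal protein list (40.2% once placed) was called in 20 of 20 runs, and no list was called in 20 random draws. A share of 38% planted in the Notch list alone (38.1% once placed) was called in 0 of 20 runs. Each run planted the same number of members, so the unadjusted p of that list was the same in all 20. The runs with a planted list therefore do not measure how often such a share would be called.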

Results

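Binding of pebbled (peb), the zinc finger transcription factor also known as hindsight and the fly homologue of mammalian RREB1, was mapped by ChIP-seq in whole Drosophila melanogaster embryos aged 0 to 24 h. The embryos carried a transgene that makes peb fused to eGFP, and chromatin was precipitated with an antibody against GFP. There was 1 group with 2 biological replicates and no second condition, so the design asks where in the genome the tagged protein was found and how well the replicates agreed. The measurements are peaks on the dm6 assembly, each with a summit and the authors' signal value, which was used here to rank peaks within a list. The lists hold no read counts, so the sequencing depth behind each replicate is unknown here.

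The larger of the lists of the whole experiment, called the optimal list here and used for the main results, held 2845 peaks with a median width of 324 bp and a total length of 869 kb. Of these, 2841 lay on the 7 main chromosomes. The other list of the whole experiment, which the authors named conservative, held 2689 peaks. Replicate 1 alone gave 1418 peaks and replicate 2 alone 2054. The signal value in the optimal list ran from 2.04 to 1055, with a median of 73.6.

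Of the 5 strongest peaks, 4 lay within 1000 bp of a protein-coding gene's start. The highest signal of all, 1055, was at chromosome X, 2703726 to 2704029, with its summit 34 bp upstream of a transcription start site (TSS) of Ugalt, which encodes a UDP-galactose transporter. The same summit was within 1000 bp of a TSS of eIF2Bbeta, a translation initiation factor gene, and the values there were 444 in replicate 1 and 617 in replicate 2. The strongest peak outside the promoter class, with a signal of 938, was at chromosome 2L, 6612562 to 6612873, in an intron of CG11050, with its summit 1016 bp downstream of the TSS. CG14100 followed with 892 (3L, 19590478 to 19590766, summit 91 bp from the TSS). The Polycomb group gene ph-p had a peak of 869 (X, 2137202 to 2137513, in an intron of the annotation, summit 496 bp from the TSS) and CG7601 one of 804 (3R, 29736707 to 29736981, intergenic, a promoter peak).

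Among the 15 strongest promoter peaks that overlapped a peak of both replicates, 12 had their summit within 132 bp of the TSS. Genes of the mitochondrial ribosome were among them, namely mRpL41 with a signal of 781 (2R, 15217604 to 15217894) and mRpS10 with 752 (3R, 15229390 to 15229685). So was PNPase, which encodes an RNA-degrading enzyme, with 705 (3R, 31404526 to 31404799, in the 5′ UTR). Genes for chromatin proteins and transcription factors were Adf1 with 744 (2R, 6662910 to 6663215, in an intron, 785 bp from the TSS), Chro with 697 (3L, 22878768 to 22879036, in the 5′ UTR) and HmgZ with 665 (2R, 21703249 to 21703599, in an intron, 565 bp from the TSS). The rest were Tcs5 with 801, CenG1A with 702 (a peak shared with the promoter of mRpS23), CG18549 with 696, CG8320 with 686 and CG5611 with 574. For all the genes named in this paragraph, the signal value of each replicate lay between 266 and 425.

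The replicates shared most of their peaks. Of the 1418 peaks of replicate 1, 1167 (82.3%, exact 95% interval 80.2 to 84.3%) overlapped a peak of replicate 2 by 1 bp or more, against 0.884% under random placement on the same chromosome. In the other direction, 1142 of 2051 peaks on the main chromosomes (55.7%, 53.5 to 57.8%) overlapped, against 0.608%. Both shares exceeded every random placement (two-sided permutation p = 0.002 each, the smallest that 1000 placements can give). Across 1129 matched pairs the signal values of the replicates had a Spearman rho of 0.80 (permutation p = 1e-05, the smallest that 100000 resamples can give), and the median distance between their summits was 20 bp. This correlation is across peaks, which are not independent replicates. Ranked by IDR score instead, which is capped at 1000, the pairs gave a rho of 0.15.

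**Figure D1:**
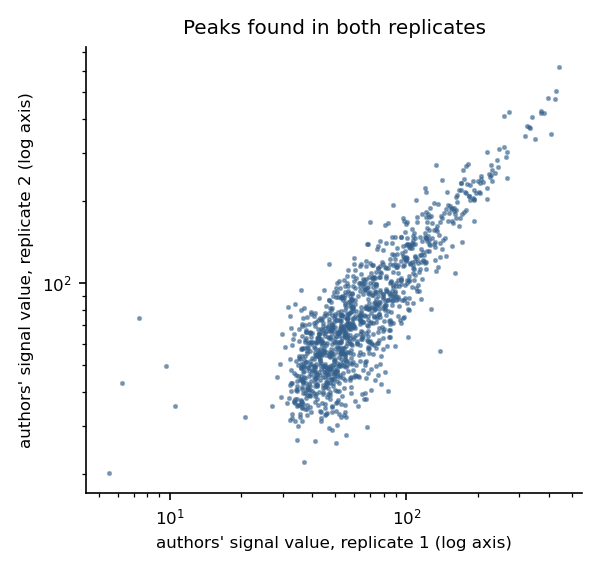
Each point is 1 of the 1129 peaks found in both replicates, with the authors' signal value in replicate 1 on the horizontal axis and in replicate 2 on the vertical axis, both logarithmic. The points follow a rising band, with a Spearman rho of 0.80.

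Peaks found in a single replicate were weaker and lay less often at promoters. In replicate 2, the 909 unshared peaks had a median signal of 40.4 against 70.4 for the shared ones, and 50.5% against 59.3% were within 1000 bp of a TSS (Fisher's exact p = 8.25e-05). In replicate 1, the 251 unshared peaks had a median signal of 37.2 against 57.4, and 52.6% against 59.6% were at promoters (Fisher's exact p = 0.0409). Most unshared peaks, 90% for replicate 1 and 93.9% for replicate 2, overlapped an entry in the other replicate's full ranked list. The full ranked lists are long, with 68609 entries in replicate 1 and 49814 in replicate 2, and no random share is given for this overlap. Part of it may therefore arise by chance. The strongest unshared peak of replicate 1, with a signal of 191, lay 940 bp downstream of a TSS of CG9663 (2L, 3302059 to 3302270), and replicate 2 had an unshared peak of 89.5 beside it, at 3302324 to 3302527. The others that were singled out were near CG10802 (76.0) and Ac13E (71.6) in replicate 1, and near CG33752 (114) and CG43245 (93.9) in replicate 2.

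Promoters held more than 50% of all summits. Of the 2841 summits, 1524 (53.6%, exact 95% interval 51.8 to 55.5%) lay within 1000 bp of the TSS of a protein-coding gene, against 20.3% ± 0.729 (SD over 1000 random placements), an excess of 2.64-fold (permutation p = 0.002). Upstream positions prevailed, with 1159 summits upstream of the nearest TSS and 365 downstream of it. There were 875 summits (30.8%) within 200 bp of a TSS and 600 (21.1%) more than 5000 bp away. Introns outside promoters held 864 summits (30.4% against 36.9% at random) and intergenic sequence 361 (12.7% against 26.3%). Coding exons outside promoters were nearly free of summits, with 8 (0.282% against 10.7%), and 3′ UTRs outside promoters held 19 (0.669% against 3.86%). The 5′ UTRs outside promoters held 4 (0.141% against 0.463%) and other exons 61 (2.15% against 1.42%). Each class differed from random placement, with Benjamini-Hochberg adjusted permutation p values of 0.0028 to 0.00599. The excess in other exons ended in the peaks of replicate 2 alone (adjusted permutation p = 0.689), and the deficit in 5′ UTRs in those of replicate 1 alone (0.0879) and with promoters of 500 bp (0.128).

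**Figure D2:**
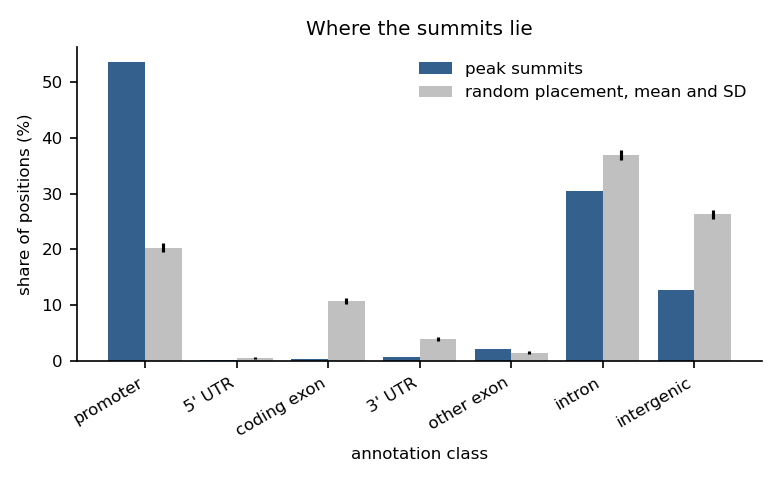
Bars show the share of the 2841 summits, in percent, in each annotation class beside the mean share under 1000 random placements on the same chromosomes, whose error bars are 1 SD. Promoters hold 53.6% of summits against 20.3% at random, and coding exons outside promoters 0.282% against 10.7%.

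Peak density differed between chromosomes (chi-square of 106 on 6 degrees of freedom against chromosome length, and 19.0 against the length covered by ranked peaks). The large arms carried 21.9 peaks per Mb on 2L, 20.6 on 2R, 22.1 on 3L and 19.6 on 3R. The X chromosome, where peb itself lies, carried 23.4 per Mb, which was 1.11 times the density of the autosomal arms (interval 1.01 to 1.22, exact binomial p = 0.0237). This ratio was 1.10 in replicate 1 alone (exact binomial p = 0.175). On the main chromosomes, 67 ranked peaks past the score threshold were absent from the thresholded optimal list. Of these, 40 lay on 3R, 23 on 2L, 3 on 3L, 1 on 4 and 0 on X. Their absence lowers the densities of 3R, 2L and 3L but not that of X, so part of the X excess may come from it. The ratio was not tested with these peaks included. Chromosome 4 had 7 peaks (5.19 per Mb) and Y had 0 of 2841, an exact upper limit of 0.13% of all peaks.

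The peb gene carried peaks at its own promoter. Within the gene (FBgn0003053, chromosome X, 4617564 to 4627206, plus strand) and 5000 bp either side there were 3 peaks, all upstream of the TSS and intergenic. The strongest, with a signal of 102 at 4616859 to 4617182, had its summit 543 bp upstream and ranked 854 in the list; its values were 42.7 in replicate 1 and 62.9 in replicate 2. A peak of 74.4 at 4614334 to 4614657 had its summit at -3068 bp and was also found in both replicates. The remaining one, of 24.9 at 4617061 to 4617384, overlapped the strongest. Over a window of 49643 bp around the gene, the full ranked lists held 52 peaks in replicate 1 and 42 in replicate 2, against medians of 24 and 17 for windows of that size on X. These counts were 2.17 and 2.47 times the medians and stood at percentiles 99.9 and 99.9 of such windows, a measure chosen after the values were seen.

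**Figure D3:**
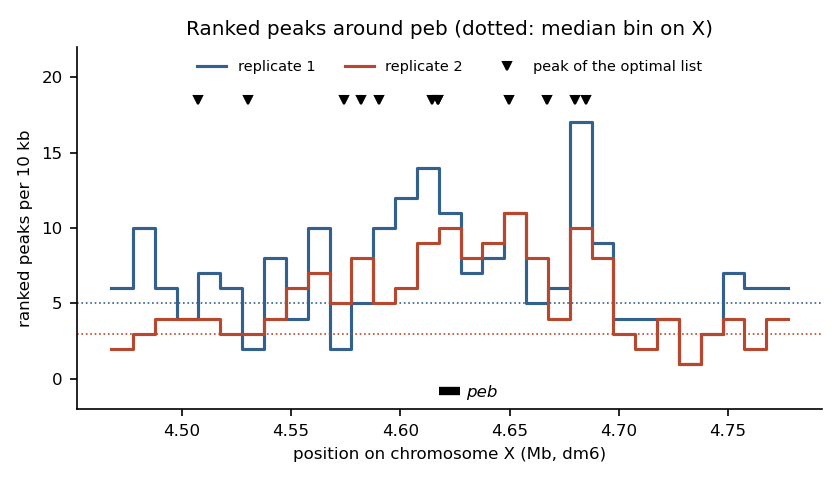
Lines show the number of peaks per 10 kb in the full ranked list of each replicate along chromosome X around peb (black bar), dotted lines the median of such bins on X (5 in replicate 1, 3 in replicate 2), and triangles the summits of the optimal list. The bin that ends at the peb TSS held 14 peaks in replicate 1 and 9 in replicate 2, but the densest bins shown lay beyond the gene, with 17 in replicate 1 (4677564 to 4687563) and 11 in replicate 2 (4647564 to 4657563).

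Of 13945 protein-coding genes on the autosomes and X, 1877 (13.5%) had a summit within 1000 bp of a TSS. Cytoplasmic ribosomal protein genes stood highest among 27 gene lists, with 37 of 92 bound (40.2%, exact 95% interval 30.1 to 51%) against 13.3% of other genes (Fisher's exact test, adjusted p = 4.31e-09). The strongest of them were RpL32 with a signal of 205, RpL34b with 178, RpS27 with 171 and RpL7 with 170, and the bound members had a median signal of 74.5. Replicate 2 alone bound 33 of the 92, whereas replicate 1 alone bound 11 of them (12% against 7.67% of other genes, Fisher's exact test, adjusted p = 0.828), so the call was lost without replicate 2. Proteasome subunit genes and their paralogues were bound in 2 of 48 cases, Rpn3 with 124.7 and Rpt5 with 60.5 (4.17%, Fisher's exact test, adjusted p = 0.22). The Rpt5 peak overlapped no thresholded peak of either replicate alone.

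Genes of the Notch pathway were bound more often than others, in 8 of 21 cases (38.1% against 13.4%, Fisher's exact test, adjusted p = 0.0381). The strongest were numb, an inhibitor of Notch signalling, with a signal of 242, then E(spl)m3-HLH with 102 and E(spl)m7-HLH with 86.3, which encode repressors of the Enhancer of split complex, and fng, a glycosyltransferase that modifies Notch, with 80.4. The other 4 were E(spl)mdelta-HLH (79.3), neur (67.3), kuz (50.6) and Nct (47.7). The peaks at E(spl)m3-HLH and E(spl)m7-HLH lay close together on 3R (26021278 to 26021601 and 26036544 to 26036867). The tests count such neighbouring genes as independent, which they may not be. With random lists matched on gene length and number of TSSs the adjusted permutation p was 0.0522, a value near the threshold that depends on the draw. It was 0.179 in the peaks of replicate 2 and 0.11 in those of replicate 1 (Fisher's exact test, 6 of 21 members each), while the ratio to other genes was 2.67 and 3.73 there against 2.84 in the optimal list. The call was also lost in the conservative list (ratio 2.19), within 500 bp of a TSS (2.55), with the nearest TSS (2.00) and with a score of 1000 (2.86; adjusted exact p = 0.213, 0.219, 0.145 and 0.0526).

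Odorant and gustatory receptor genes were bound less often than other genes, in 2 of 119 cases (1.68% against 13.6%, Fisher's exact test, adjusted p = 0.000135), namely Gr32a (86.5) and Or88a (85.3). In replicate 1 alone the ratio to other genes stayed low at 0.217 (1.68% against 7.75%), with an adjusted exact p of 0.115. Larval and adult secreted protein genes were bound in 0 of 20 cases and Hox genes with their cofactors in 0 of 11; the exact upper limits of these shares are 16.8% and 28.5% (Fisher's exact test, adjusted p = 0.331 and 0.789, unadjusted 0.0982 and 0.38). With each peak given to its nearest TSS at any distance, 6 of the 11 genes of the Hox list were bound (54.5% against 14.3%, Fisher's exact test, adjusted p = 0.00792). By peaks within the gene or 2000 bp of it, 3 of 11 were bound (27.3% against 22.9%, adjusted exact p = 0.836). The nearest-TSS count was not matched on gene length. For peaks within the gene or 2000 bp, random lists matched on gene length and number of TSSs gave a ratio of 0.620 (adjusted permutation p = 0.751). That matched test was added after the values were seen.

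The other lists did not pass the threshold at promoters (24 lists with adjusted p of 0.0713 or more by Fisher's exact test). Genes of the JNK pathway and dorsal closure, the process in which hindsight acts in the amnioserosa, were bound in 6 of 16 cases: jar (128), aop (70.1), bsk, the JNK itself (60.5), msn (59.9, the peak also assigned to RpL8), Rho1 (53.2) and kay (52.9). EGF and FGF receptor signalling genes were bound in 8 of 24 cases, led by the ligand spi (171) and Mkp3 (118), followed by aop and Krn (66.5). Actin and morphogenesis genes were bound in 6 of 20 cases, led by Act5C (142), sqh (91.4), tsr (54.2) and Rok (54.1, the peak also assigned to RpS19a). Amnioserosa genes were bound in 2 of 13 cases, peb itself and ush (54.6), but in 6 when each peak was given to its nearest TSS (46.2% against 14.3%, Fisher's exact test, adjusted p = 0.0131) and in 6 by peaks within the gene or 2000 bp of it (46.2% against 22.9%, adjusted exact p = 0.172). Against matched random lists, the latter count gave a ratio of 1.37 (adjusted permutation p = 0.751), and the nearest-TSS count was not so matched. Of the 7 genes linked with hindsight in the literature, peb alone was bound at its promoter. Of the rest, ct had 3 peaks within the gene or 2000 bp of it, the strongest in an intron (68.8, X, 7618212 to 7618535, 9226 bp from the TSS), and puc had 2, the strongest in an intron (97.8, 3R, 8113967 to 8114290, 7641 bp from the TSS). There was no peak within 2000 bp of nvy, jbug, stg or lz.

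In the BMP pathway 4 of 17 genes were bound, Mad (232), brk (88.9), wit (64.5) and dally (55.8), and in the Wnt pathway 3 of 21, sgg (169), nkd (87.9) and fz3 (47.2). The hedgehog list had 2 of 12, ci (55.3) and ptc (49.6), and the JAK/STAT list 1 of 12, Stat92E (107). Peripheral nervous system genes had 4 of 18, elav (276), cpo (95), neur and da (59.2), and central nervous system genes 3 of 26, brat (324), Lim1 (61.2) and D (49.7). Mesoderm regulators had 4 of 19, tin (222), mbc (102), lbe (52.5) and rols (44.9), and muscle structural genes 2 of 15, Msp300 (134) and sls (114). Epithelial junction genes had 4 of 17, par-6 (110), dlg1 (88.6), crb (63.2) and Mcr (37.4). Tracheal genes had 3 of 17, apt (72.6), trh (65.8) and bnl (63.3), gut genes 2 of 14, bowl (246) and fkh (83.8), and segmentation genes 2 of 22, bcd (67.4) and odd (47.3). Cell cycle genes had 3 of 18, CycE (53.3), fzr (49.5) and Cdk4 (47.8), germline genes 2 of 12, Sxl and bgcn (55.5), ecdysone genes 1 of 17, Eip75B (113), and haemocyte genes 1 of 14, ush. The peaks of dally, fz3, ci, ptc, Lim1, lbe, rols, Mcr, odd, Cdk4 and ush overlapped no thresholded peak of either replicate alone. When a peak anywhere within the gene or 2000 bp of it counted as bound (22.9% of all genes), 7 lists stood above other genes, among them BMP with 13 of 17, JNK and dorsal closure with 12 of 16, EGF and FGF with 13 of 24, Wnt with 12 of 21 and actin and morphogenesis with 10 of 20 (Fisher's exact test, adjusted p = 3.89e-05, 9.83e-05, 0.00336, 0.00328 and 0.0246). Against random lists matched on gene length and number of TSSs, a test added after these values were seen, the ratios were 2.21, 1.78, 1.53, 1.62 and 1.25 (adjusted permutation p = 0.0054, 0.054, 0.265, 0.205 and 0.751). The Notch (12 of 21, ratio 2.10) and ribosomal protein lists (42 of 92, 2.13) also stayed above the matched lists (adjusted permutation p = 0.0283 and 0.0027).

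**Figure D4:**
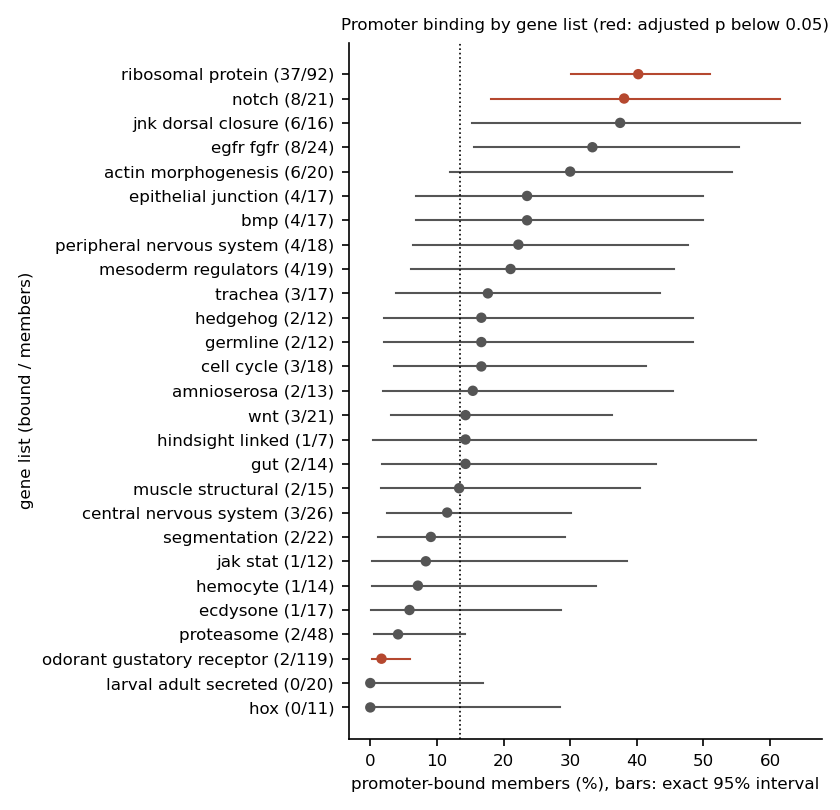
Points show the share of the members of each of the 27 gene lists, in percent, with a summit within 1000 bp of a TSS, bars the exact 95% interval, and the dotted line the share of all protein-coding genes, 13.5%. Ribosomal protein (40.2%) and Notch genes (38.1%) lie above the line and odorant and gustatory receptor genes (1.68%) below it, each with an adjusted p below the threshold.

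Under the summits, 2 of 15 known sequence patterns were more frequent than in flanks 1000 bp away. The DNA replication-related element TATCGATA was in 2.57% of the sequences 100 bp either side of summits against 0.474% of 5490 flanking ones, and the M1BP site GGTCACACT in 0.986% against 0.291% (Fisher's exact test, adjusted p = 1.02e-14 and 0.000596). In controls matched on GC content and TSS distance they were in 1.14% and 0.352%, so the ratio for TATCGATA was 2.25 there against 5.43 with flanks. Both are known from promoters of broadly expressed genes. The RREB1 core sequence CCCCAAAC was in 13 of 2841 summit sequences (0.458% against 0.729%, Fisher's exact test, adjusted p = 0.279; ratio 0.628, and 1.24 with controls matched on GC content and TSS distance), and the longer RREB1 pattern CCCAMMCMMCC in 4 (0.141% against 0.328%, adjusted exact p = 0.291), though in none of replicate 2 alone (adjusted exact p = 0.0133). The patterns CACACACA, TGGGAA, CACATG and AACCGCA were less frequent at summits (3.70% against 5.10%, 10.1% against 12.2%, 7.11% against 9.31% and 1.41% against 2.60%). The other 7 patterns, those of GAGA factor, Zelda, GATA factors, Grainyhead, Stat, AP-1 and scalloped, did not pass the threshold (adjusted p of 0.151 or more by Fisher's exact test). None of the 4 lower ones passed when controls were matched on GC content and TSS distance, where the GAGA factor pattern GAGAGAG was higher (4.58% against 2.22%, Fisher's exact test, adjusted p = 7.68e-08).

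The open search over 2080 6-mers was led by AT-rich sequence. TTAAAA was in 48.8% of summit sequences against 27.0% of flanks (Fisher's exact test, adjusted p = 1.27e-82), and each of the 10 leading 6-mers consisted of A and T alone. Summit sequences had a mean GC content of 36.4% and flanks one of 42.6%. Against controls matched on GC content and TSS distance (36.5% GC), the leading 6-mer was ACAGTG, present in 21.2% of summit sequences and 7.02% of controls (Fisher's exact test, adjusted p = 4.87e-73). It ranked 12 against flanks, where its control share was 8.27%. Of the 10 leading 6-mers under matched controls, 5 held CAGTG on either strand, among them CAGTGC (17.2% against 7.0%), ACACTG (17.2% against 7.18%) and CAGTGG (15.9% against 6.71%). The matched control was set out as an alternative before the data were examined, whereas ACAGTG was singled out after its values were seen, as were the measurements of its position.

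ACAGTG was densest beside the summit, mostly in the orientation that reads towards it. With the strongest peak of each cluster of summits within 1000 bp (2544 peaks), its density was 0.817 per kb within 50 bp of the summit, 1.79 per kb at 51 to 100 bp and 0.437 per kb at more than 200 and up to 500 bp. Of the 517 sites 41 to 100 bp from a summit, 409 (79.1%, exact 95% interval 75.3 to 82.5%) read 5′ to 3′ towards it and 108 away from it (exact binomial p = 3.2e-42). The share was 77.3% in replicate 1, 79.3% in replicate 2, 76.8% at promoters and 81.2% elsewhere, and 48.7% for the 667 sites more than 200 and up to 500 bp away (exact binomial p = 0.536). The median distance of the 409 directed sites from the summit was 76 bp, a value bounded by the chosen range of 41 to 100 bp. It is therefore not a measure of spacing. Sites that read towards the summit were also frequent farther out, with 117 at 100 to 120 bp and 99 at 120 to 140 bp. In the 409 sites, G followed the 6-mer in 59.2% of cases, the base just before it was most often C (41.8%) and the base before that most often G (54.8%). TTAAAA was densest around the summit, at 5.42 per kb against 1.84 per kb at more than 200 and up to 300 bp.

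**Figure D5:**
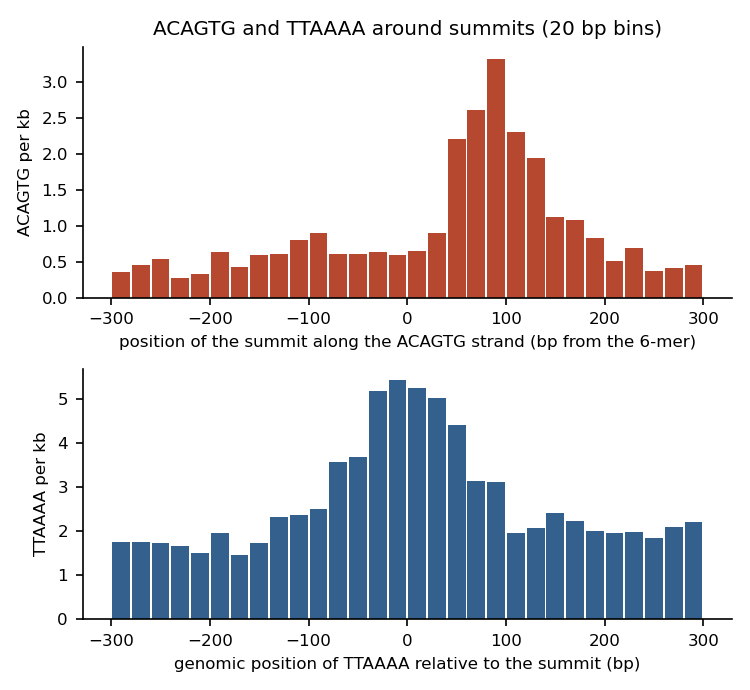
The upper bars show the density of ACAGTG per kb by the position of the summit along the strand of the 6-mer in bp, and the lower bars that of TTAAAA by its position relative to the summit, around 2544 summits in bins of 20 bp. ACAGTG is densest, at 3.32 per kb, where the summit lies 80 to 100 bp after it, and TTAAAA is densest at the summit itself.

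Stronger peaks lay more often at promoters and held both 6-mers more often. In 4 equal bins from strongest to weakest, the share within 1000 bp of a TSS was 63.6, 50.3, 50 and 50.7% (Spearman rho 0.093 across peaks, adjusted permutation p = 6e-05), so the difference lay in the strongest bin. The share with TTAAAA was 55.8% in the strongest and 40% in the weakest bin (rho 0.12, adjusted permutation p = 6e-05) and that with ACAGTG was 25.3, 20, 23.0 and 16.3% (rho 0.062, adjusted permutation p = 0.00391). In the peaks of replicate 2 alone the rho for ACAGTG was 0.053 (adjusted permutation p = 0.063). TATCGATA went the other way, from 1.41 to 4.08% (rho -0.060, adjusted permutation p = 0.00479), as did CACACACA, from 2.39 to 6.76% (rho -0.10, adjusted permutation p = 6e-05). So did GAGAGAG, from 3.94 to 7.46% (rho -0.052, adjusted permutation p = 0.0162), and AACCGCA, from 0.703 to 2.68% (rho -0.0495, adjusted permutation p = 0.0203).

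The optimal and conservative lists were not nested. Of the optimal peaks, 434 overlapped none of the conservative list, and 288 conservative peaks overlapped none of the optimal list. The peaks found in the optimal list alone were weaker, with a median signal of 48.9 against 81.4 for the shared ones. Their share at promoters was 51.2% against 54.1% (Fisher's exact p = 0.272), and their share with ACAGTG 17.7% against 21.8% (Fisher's exact p = 0.0639).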

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

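The tests of ACAGTG on chromosomes not used to pick it, of the orientation of ACAGTG, of lists of widely used genes and of the density of ranked peaks at peb were chosen only after the results were seen.

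Peaks outside the thresholded lists stood out in the data that the comparisons do not use. In the ranked list behind the optimal list, 68 peaks (2.33% of those past the score of 830) were absent from the thresholded list. The strongest of them had a signal of 1028, which ranks 2 in that ranked list (2L, 480938 to 481245, summit at -1412 bp from the TSS of cbt). On the main chromosomes these peaks lay on 3R (40), 2L (23), 3L (3) and 4 (1), and 32 of the 67 were within 1000 bp of a TSS; they include peaks near Lk6 (545), larp (368) and trx (265). A further 4 peaks of the optimal list lay on unplaced scaffolds of X, with signals from 2.56 to 76.2, and entered no test.

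ACAGTG was the leading 6-mer against controls matched on GC content and TSS distance both on 2L with 2R and on the other chromosomes. Its lower ratio on chromosomes not used to pick it was 3.04, so its lead did not come from the picking alone. Both parts used controls matched in the same way, so the split cannot decide on base composition beyond the matched GC content. At summits over 1000 bp from a TSS of a protein-coding gene, ACAGTG was 3.30 times as frequent as in matched controls. Sequence within 1000 bp of such TSSs therefore does not alone account for it. Promoters of non-coding genes were not excluded, and controls were not matched on open chromatin, so a wider feature of regulatory sequence was not tested. The density within 50 bp of the summit was 1.87 times that at more than 200 and up to 500 bp, between the bounds set for and against a protein held at the sequence itself, and the site is denser farther out. Since 79.1% of the sites 41 to 100 bp away point at the summit, a candidate explanation is a protein held on 1 side of the sequence, over the AT-rich stretch; whether that is peb or a partner was not tested.

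The excess of ribosomal protein promoters may be a property of replicate 2. With lists of equal length (1418 peaks), replicate 2 bound 24 of the 92 genes and replicate 1 bound 11, of which 9 were shared (exact McNemar p = 0.00235). Peaks near the threshold are not the whole of it, since the ratio to other genes was 2.67 in the stronger part of the optimal list, though it was 3.43 in the weaker part. In the optimal list, wide use alone did not go with such a share in the gene lists at hand. Proteasome genes without their T and R paralogues (ratio 0.464), initiation factors (1.01), tRNA synthetases (1.39) and mitochondrial ribosomal proteins (1.53) together had a ratio of 1.19. They were bound in 16% of cases (exact 95% interval 11.0 to 22.2%) against 40.2%. In replicate 1 alone, the ratio was 1.79 for mitochondrial ribosomal proteins (10 of 73) and 1.56 for ribosomal proteins (11 of 92). The contrast with that list was therefore absent there. The lists of widely used genes were put together after results were seen and were not matched on expression level, so other traits of widely used genes were not tested. What differs between the replicates, such as embryo ages within 0 to 24 h, stays open, and no biological explanation of that difference was tested because there is 1 group.

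The window around peb stood at percentiles 99.9 and 99.9 of windows on X for ranked peaks, and the densest window of that size on X overlaps it in each (4586001 to 4635643 in replicate 1, 4603001 to 4652643 in replicate 2). Whether the region is also rich in strong sites cannot be told: the optimal list had 3 peaks there, percentile 83.7 and under the bound of 95 set against it, but the exact 95% interval of a count of 3 (0.619 to 8.77) reaches percentile 99.5, so the bound was too narrow for so few peaks (percentile 95.7 in replicate 1 and 89.1 in replicate 2). Extra copies of the region in the tagged line stay open as a candidate explanation, since reads from a transgene with the gene and its surroundings would map there; the percentile drew attention to the region and so decides nothing, and the densest bins of 10 kb lay beyond the gene (17 peaks in replicate 1, 11 in replicate 2). Open chromatin with many weak sites also stays open, because read coverage and controls were not analysed here. No biological explanation was tested.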

How the results depend on the processing

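The alternatives of a score of 1000, of clusters, of a signal of 20 or more, of the other replicate's ranked list and of the peak number of single replicates, and all values for X against the autosomes and for ACAGTG, were chosen after seeing the data; the rest were planned. Of 113 values for the designed results under alternatives, 89 kept their direction and side of the threshold (counts, within 1.5 times), including all for replicate overlap (from 49.2 to 98.2%), TSS-proximal share (from 43.3 to 64.2%) and rank agreement (rho from 0.15 to 0.80). Of 413 values for single gene lists, patterns and 6-mers, 363 did, where a turn in direction between values that both missed the threshold counts as kept. The planned score of 830 equals the authors' own threshold and removed no peak, so it tests nothing. No paired analysis was possible because there is 1 group. The cause was not tested for any change given here. Read depth is unknown, which limits what can be said of weak peaks.

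Leaving out a replicate gave 1418 to 2054 peaks, 0.0975 to 0.141% of summits in 5′ UTRs, 1.56 to 2.75% in other exons, an X to autosome ratio from 1.10 to 1.12 and a rho for ACAGTG from 0.053 to 0.10. It gave 0 to 1 enriched and 0 to 1 depleted gene lists by Fisher's exact test (main 2 and 1). In replicate 1 alone, where both counts were 0, 1 list was enriched and 1 depleted at an unadjusted p under the threshold. Enriched patterns then numbered 1 to 2 and depleted ones 2 to 5 (main 2 and 4). With promoters of 500 bp, 0.528% of summits lay in 5′ UTRs.

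Enriched lists numbered 1 with the conservative list, within 500 bp, with a score of 1000 and with matched random lists, 7 with gene bodies and 2000 bp, and 16 with the nearest TSS. The adjusted p of the Notch list ran from 0.00328 to 0.219 over its alternatives (exact and permutation tests). With the nearest TSS, ratios to other genes turned from below to above 1 and passed the threshold for JAK/STAT (3.50), central nervous system (2.43), Hox (3.82), segmentation (2.55) and ecdysone (2.89). The nearest-TSS ratios were not matched on gene length or number of TSSs. Enriched patterns numbered 1 with 50 bp either side of summits. Depleted patterns numbered 2 with the conservative list and with a score of 1000, 1 with 200 bp either side, and 0 with matched controls by Fisher's exact test (2 at an unadjusted p). CACACACA turned to a ratio of 1.10 with 200 bp either side and 1.14 with matched controls. Matched controls gave 227 enriched and 257 depleted 6-mers against 460 and 904.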

Other observations

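The tests in this part were all chosen after the data had been seen.

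Many of the leading longer words held CAGTG. Among 8-mers under the strongest peak of each cluster, 216 of 32896 were more frequent than in matched controls by Fisher's exact test, led by CACAGTGG (5.78% against 0.767%), CACTGAGA (4.99% against 0.59%) and CACTGTGC (5.54% against 0.865%). Others lacked CAGTG on both strands, among them CTGAGAGA (2.95% against 0.354%), GAGAGAAA (4.87% against 1.22%) and CAGGGGCG (1.38% against 0.0393%). Of these, CTGAGAGA shares CTGAGA with CACTGAGA and GAGAGA with GAGAGAAA, so these words may be shifted pieces of a longer one. Whether the words without CAGTG lie in the same windows as ACAGTG was not tested. In the 500 strongest peaks, 28.6% of summit sequences held ACAGTG against 7% of matched controls.

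Some summits lay near small nuclear RNA genes and other non-coding RNA genes. There were 5 summits within 200 bp of 1 of the 32 snRNA genes (0.176% against 0.015% at random, adjusted permutation p = 0.005), 219 near the 3289 genes of the ncRNA class (7.71% against 4.56%, adjusted permutation p = 0.005) and 5 near the 290 tRNA genes (0.176% against 0.0902%, adjusted permutation p = 0.4). Random placement did not hold fixed the distance to protein-coding TSSs, near which summits were in 2.64-fold excess. Whether these genes stand out beyond that excess was not tested. Cytochrome P450 genes were bound at promoters in 2 of 83 cases (2.41% against 13.5%, Fisher's exact test over 6 lists, adjusted p = 0.00615). The other lists did not pass the threshold: tRNA synthetases (6 of 32), translation initiation factors (6 of 44), tetraspanins (7 of 34) and Toll and immune peptide genes (2 of 26, a list that was narrowed after it was seen to take unrelated genes).

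Since mRpL41 and mRpS10 were among the strongest peaks, the hypothesis that mitochondrial ribosomal protein promoters are bound more often than others was tested. They were bound in 15 of 73 cases, a ratio of 1.53 to other genes (Fisher's exact p = 0.0843, adjusted 0.253), which leaves the hypothesis open. The list holds mRpL41 and mRpS10, the genes that prompted the test. The ratio was 1.79 in replicate 1 (unadjusted Fisher's exact p = 0.0724), 1.54 in replicate 2 (0.127) and 1.94 in the stronger part of the optimal list (0.0282). mRpS23 (702, the peak also assigned to CenG1A) and mRpL23 (524) were also among the bound.

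Some thresholded peaks had very low signal values. In the optimal list 129 peaks on the main chromosomes were under 20, and 127 of them (98.4%) had a stronger peak within 1000 bp, at a median distance of 202 bp, against 5.97% of the other 2712. Within 50 bp of their summits, 10.1% held ACAGTG against 3.84% of matched controls (Fisher's exact p = 0.0021) and 7.49% of the other summits.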
